A study of Homo sapiens with 11 samples.

How the data were processed

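RNA-seq libraries were made from polyadenylated RNA of H1 cells with a strand-marking dUTP protocol, per the labels' protocols, with 2 libraries from hESCs in mTeSR1 and 2 after 48 h of 50 ng/ml activin in RPMI-B27. Genome build hg18 and the tools TopHat and Bowtie are named for these samples per the submitters' processing notes, with no versions. The deposited expression table gives RPKM, reads per kilobase of transcript scaled to the total of mapped reads, computed by the authors for RefSeq mRNA transcripts, with 1 column per condition per the file headers. Which of the libraries entered a column, and how, is not given in the sources used here. No column of per-sample values was left unused. The deposited pools of assembled RNA list records with hg18 start, end, strand and exon blocks, 1 pool for hESCs and 1 for differentiated cells, per the file headers. Record names point to the assemblers Cufflinks and Scripture; versions and settings are not given in the sources used here. GRO-seq and ChIP-seq samples were not analysed here.

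The planned tests between replicates (limma with camera and fry, a replicate block and leaving out each library) needed a value per library and were replaced by fold sizes with no test, as set in advance for this case. Per gene name the transcript row with the highest mean RPKM was kept, and genes with a mean of at least 0.5 RPKM were compared as log2(RPKM + 0.5), 48 h minus hESC. A 2-fold difference on that scale is called higher or lower. The 25 gene lists were fixed before the data were examined. For each list of at least 5 tested genes, the median was set against 10000 random lists with the same number of genes in each of 20 bins of mean RPKM, and called apart outside the central 95%. Random genes were drawn independently, so this range makes no allowance for genes that vary together. No allowance was made for the number of lists either. The rule for named genes took the 12 highest and 12 lowest log2 fold changes with at least 2 RPKM in the higher condition, up to 4 members per list with the largest differences past 2-fold (the 2 members with the highest mean RPKM were added where fewer than 2 passed), and 14 markers. This rule was written for genes past an adjusted p-value and was applied with the 2-fold threshold in its place. For divergent records, the 10 genes with the largest differences in each class with a record in 1 pool alone were listed, and the text names part of them. Some genes that the rule names are not reported here. Named pseudogenes were counted from a RefSeq gene table by symbol, used for names and gene classes only; 13038 of 13049 genes matched it.

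RPKM is not a count, and no count test was run. Because the authors counted whole reads, a transcript length and the total reads of a column could be found at which both values of a row are whole reads. At totals of 309476000 and 210155000 reads this held for 100% of 30848 rows with a value above 0, within 0.003 reads plus the rounding of the file. Wrong totals were tried on 588 rows. Of those with many reads, 9.41% came out whole at a length no longer than the one found. That criterion is narrower than the one behind the 100%, so these shares are not directly comparable. The recovered length is the shortest that fits. On 588 simulated rows it equalled the true length or a divisor of it in 98.0%, so recovered reads and lengths are lower bounds and intervals from them are, if anything, too wide. A value of 1 read per kb was 0.00323 RPKM in hESC and 0.00476 RPKM at 48 h. These lengths were also the ones used wherever lists were matched on transcript length. By the recovered reads, which are lower bounds, the tested genes held 63.6% and 64.1% of the reads. Ratio intervals are exact Clopper-Pearson intervals on these reads at 95% and cover counting error only. Reads from PCR-amplified libraries without molecular identifiers are not independent molecules.

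Fold calls, pair correlation, divergent loci and length recovery were tested on simulated data. Poisson reads at the real depths over 13049 genes, 200 of them changed, gave a 2-fold call in the right direction for 96% of genes with a true log2 change of 2, for 89% of those with 1.5, and for 0 of the 12849 unchanged genes. That simulation holds no variation between cultures. A correlation of 0.5 planted in the 720 head-to-head pairs came back as 0.48. Of 300 divergent pairs planted among 4000 simulated loci, 99.7% were found at their distance.

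Pairs of mRNAs were taken with nearest ends within 2000 bp and not overlapping, and the reference was 100000 exchanges of partners. Bootstrap intervals used 2000 resamples of pairs, or of genes for ratios of gene numbers between the pools. For the pools, records without a strand and records off the numbered and sex chromosomes were left out of loci, same-strand records sharing at least 1 bp were merged, and strands were permuted 1000 times within chromosomes. For each mRNA the nearest record wholly upstream was taken, by its 5′ end on the opposite strand and by its 3′ end on the same strand. The same-strand control was first taken by the 5′ end, which gave 154 genes in hESC and 192 at 48 h. It was changed after these values were seen, because a record that may not overlap the mRNA can start near it on the same strand only if it is very short; the change raised the control and lowered the excess of divergent records. The analysis of records around mRNA genes was itself added after the data were seen. The planned lncRNA fold changes and lncRNA/mRNA correlation could not be computed, since no row of the expression table had a noncoding RefSeq accession; mRNA pairs and the presence of records took their place, chosen once the files were seen. Alternatives varied the pseudocount, the expression minimum, the scaling, the rows per gene, the windows, the splicing and the overlap. Shares carry exact Clopper-Pearson intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.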

Results

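H1 is an established human embryonic stem cell (hESC) line. The series asked how long noncoding RNAs (lncRNAs) are transcribed in hESCs and in early differentiation, with attention to lncRNA/mRNA gene pairs that start from opposite strands and run apart. Polyadenylated RNA was sequenced from H1 cells kept in mTeSR1, a medium that holds the pluripotent state, and from H1 cells after 48 h in RPMI-B27 with 50 ng/ml activin. Activin is a TGF-beta family ligand that acts through SMAD2 and SMAD3 and is used to direct stem cells to endoderm. There were 2 RNA-seq libraries per condition, but the deposited expression table held 1 RPKM column per condition, so no spread between libraries could be had. Differences below therefore have no replicate check, carry no p-value and describe these columns, not the conditions at large. The columns stood on 309476000 reads for hESC and 210155000 reads for 48 h of activin, recovered from the steps between their values. At that depth a transcript of 1 kb with 0.5 RPKM held 155 reads in hESC and 105 reads at 48 h. Intervals on RPKM ratios below are 95% exact binomial intervals on those reads and cover counting error only. The table held 33483 transcript rows of 19077 genes, all with RefSeq accessions of the mRNA class (NM), and 13049 genes with a mean of at least 0.5 RPKM were compared. Transcripts assembled from each condition's RNA came as a pool of genomic records on hg18. The 4 GRO-seq and 3 ChIP-seq samples were not analysed here.

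The first comparison asked which mRNAs differed after 48 h of activin. Targets of Nodal and activin signalling were higher as a list, led by LEFTY2. LEFTY2, a secreted Nodal antagonist (NM_001172425, hg18 chromosome 1, 224190921 to 224195706), was at 9.04 RPKM in hESC and 192 RPKM at 48 h, a ratio of 21.2 (95% interval 19.1 to 23.5). Its neighbour LEFTY1 (NM_020997, chromosome 1, 224140605 to 224143469) went from 21.8 to 225 RPKM, a ratio of 10.3 (10.1 to 10.5). CER1, another secreted antagonist made in anterior endoderm (chromosome 9, 14709732 to 14712715), was at 36.5 and 257 RPKM. NODAL itself was at 19.5 and 59.3 RPKM. Of 11 Nodal/activin target genes fixed before the data were examined, 7 were at least 2-fold higher at 48 h and none was 2-fold lower. Fold changes were taken on log2(RPKM + 0.5), which understates the change of genes with low values. The list's median log2 fold change was 1.43, above all 10000 random lists matched on mean RPKM, whose central 95% ran from -0.35 to 0.44. Here and below, random ranges make no allowance for genes that vary together or for the number of lists.

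Genes of the primitive streak and of definitive endoderm were higher with them. In the streak and mesendoderm list 9 of 16 measured genes were at least 2-fold higher and none was 2-fold lower, with a median of 1.28. T (brachyury), a T-box factor of the streak, was at 1.00 and 3.10 RPKM, a ratio of 3.09 (2.84 to 3.37). The T-box factor EOMES went from 5.16 to 14.7 RPKM, the homeobox genes MIXL1 from 8.33 to 21.8 RPKM and GSC from 5.77 to 21.3 RPKM, and the zinc finger gene SP5 from 8.67 to 33.0 RPKM. In the definitive endoderm list 12 of 17 genes were at least 2-fold higher and none was 2-fold lower, with a median of 1.20. Among them GATA6 (NM_005257, chromosome 18, 18003414 to 18036225), a zinc finger factor of endoderm, was at 2.32 and 12.5 RPKM, a ratio of 5.38 (5.15 to 5.63). SOX17, an endodermal HMG-box factor (chromosome 8, 55533048 to 55536009), was at 6.88 and 28.2 RPKM, a ratio of 4.09 (3.96 to 4.23). The forkhead gene FOXA2 was at 6.07 and 16.3 RPKM, the chemokine receptor gene CXCR4 at 6.08 and 21.3 RPKM, and CYP26A1, which degrades retinoic acid, at 12.6 and 43.4 RPKM. Both list medians lay above all matched random lists. GSC, EOMES, NODAL and CER1 stood in more than 1 of these lists.

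The pluripotency genes did not stand apart as a group. The median of the 24 genes was -0.08, at the 11.6th percentile of matched random lists. SOX2 was at 285 and 342 RPKM, a log2 fold change of 0.27, and NANOG at 17.8 and 26.4 RPKM, a log2 fold change of 0.56. NANOG has 10 named pseudogenes, which can take or lend reads. Of the list, DPPA2 was lower (6.59 and 1.30 RPKM), as were VSNL1 (30.4 and 10.6 RPKM) and TERT, the catalytic subunit of telomerase (7.20 and 2.59 RPKM). POU5F1, the gene of OCT4, depended on the transcript row. NM_002701 was at 1134 and 2420 RPKM, a log2 fold change of 1.09. The rows NM_001173531 and NM_203289, which start and end within it, had log2 fold changes of -0.15 and -0.16. POU5F1 has 6 named pseudogenes, and no direction is given for it here.

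**Figure D1:**
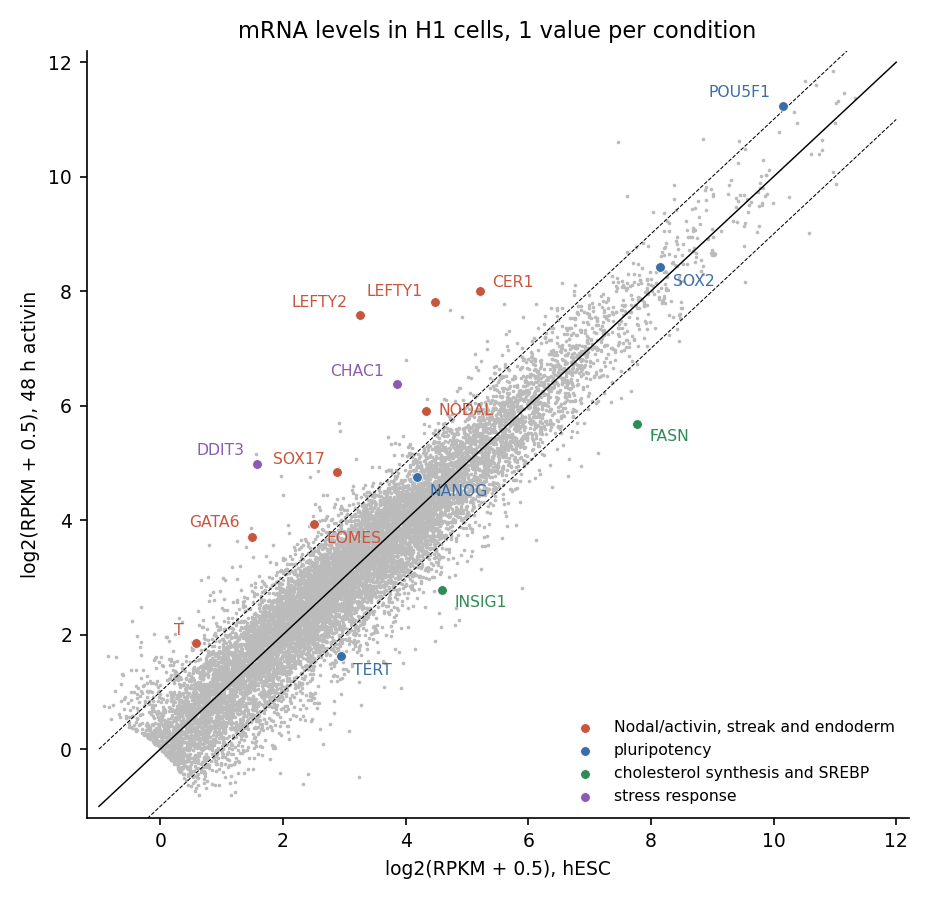
Each grey point is 1 of 13049 genes, with log2(RPKM + 0.5) in hESC on the x axis and after 48 h of activin on the y axis; the solid line marks equal values and the dashed lines a 2-fold difference. LEFTY2, LEFTY1, CER1, GATA6 and SOX17 lie above the upper dashed line, FASN below the lower one, and SOX2 and NANOG between them.

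In all, 475 genes (3.64%) were at least 2-fold higher at 48 h and 668 (5.12%) at least 2-fold lower, and 71.0% of genes lay within 1.5-fold. The median log2 fold change of all genes was 0.01. Beside LEFTY2, LEFTY1 and CER1, the 12 highest genes held DLK1, a Notch-like imprinted gene (2.46 and 35.1 RPKM), the stress factors DDIT3 (2.49 and 31.2 RPKM) and ATF5 (7.04 and 51.4 RPKM), and ODC1, the first enzyme of polyamine synthesis (15.5 and 111 RPKM). They also held the metallothionein MT1M (3.42 and 26.8 RPKM), the mitochondrial protein gene ROMO1 (26.0 and 203 RPKM), the ribosomal gene RPS29 (176 and 1555 RPKM, with 66.8 and 155 RPKM in its other transcript row) and the trypsinogens PRSS1 (0.305 and 5.11 RPKM) and PRSS2 (1.24 and 11.4 RPKM). PRSS1 and PRSS2 are close paralogs and MT1M belongs to a family of near copies, so reads may have been split among relatives. The lowest gene was TXNIP, an inhibitor of thioredoxin and glucose uptake, at 8.97 and 0.218 RPKM, a ratio of 0.0243 (0.0203 to 0.0288). Among the other 11 were ABHD12B (4.54 and 0.155 RPKM), S100A6 (14.7 and 1.60 RPKM), the cystatin CST4 (4.79 and 0.239 RPKM), RAB33A (7.90 and 0.739 RPKM), the cell cycle inhibitor CDKN1A (27.5 and 3.98 RPKM), MIR205HG (28.7 and 4.29 RPKM), PLA2G3 (21.7 and 3.19 RPKM), the neuronal genes ARC (5.79 and 0.564 RPKM) and GRIN2D (12.0 and 1.63 RPKM), and PHYHIP (9.18 and 1.20 RPKM). Taking every transcript row in place of 1 row per gene gave 786 higher and 1188 lower rows.

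Genes of sterol and fatty acid supply were lower at 48 h as a group. In the list of cholesterol synthesis genes and SREBP targets, 17 of 24 were at least 2-fold lower and none was 2-fold higher. The median of -1.31 lay below all matched random lists. The fatty acid synthase gene FASN was at 219 and 50.7 RPKM and the sterol sensor gene INSIG1 at 23.6 and 6.38 RPKM. The culture medium changed together with activin in this comparison. Besides this list 4 others had a median below the central 95% of random lists. Among 11 FGF/ERK feedback genes, whose levels follow ERK activity, 4 were at least 2-fold lower and none was higher, with a median of -0.40 at the 1.93rd percentile. These were DUSP6 (82.8 and 23.4 RPKM), SPRY4 (49.8 and 14.4 RPKM), DUSP5 (9.69 and 3.72 RPKM) and ETV4 (53.7 and 25.4 RPKM). Among 13 p53 target genes the median was -0.62 and 4 were lower, namely CDKN1A, FDXR (31.5 and 9.30 RPKM), RRM2B (20.4 and 7.33 RPKM) and TNFRSF10B (31.6 and 12.9 RPKM). Of 46 replication-dependent histone genes, 7 were lower and 1, HIST1H2BH (log2 fold change 1.57), was higher, with a median of -0.28. HIST1H2AC (11.1 and 3.65 RPKM) and HIST1H4C (52.8 and 22.3 RPKM) were among the lower ones. Most histone mRNAs of this class lack a poly(A) tail, and the libraries were made from polyadenylated RNA.

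Of 10 genes of the unfolded protein and integrated stress response, 5 were at least 2-fold higher and none was lower, with a median of 1.11 above all matched random lists. DDIT3 (CHOP, NM_001195057, chromosome 12, 56196638 to 56200567) had a ratio of 12.5 (10.9 to 14.4). CHAC1, which degrades glutathione, had a log2 fold change of 2.52, and the asparagine synthetase gene ASNS was at 39.5 and 126 RPKM and TRIB3 at 5.56 and 17.5 RPKM. Of 8 hypoxia response genes 3 were higher, namely PDK1 (4.93 and 26.4 RPKM), BNIP3 (48.0 and 218 RPKM) and VEGFA (13.1 and 29.0 RPKM). The list median was 0.70, at the 99.96th percentile. PDK1 is a brake on pyruvate oxidation in mitochondria. BNIP3 has 46 named pseudogenes. Of 13 immediate early and heat shock genes none was higher, and the near-identical HSPA1A (25.3 and 9.48 RPKM) and HSPA1B (28.2 and 8.98 RPKM) were lower, with a list median of 0.08 within the random range.

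Wnt and BMP target lists were also on the higher side, each through part of its members. Of 12 Wnt targets 4 were at least 2-fold higher, among them DKK1, a secreted Wnt antagonist (1.22 and 7.58 RPKM), LEF1 (0.525 and 2.27 RPKM) and APCDD1 (3.26 and 8.07 RPKM), with a median of 0.45 at the 99.62nd percentile. Of 8 BMP targets 3 were higher, namely MSX2 (1.12 and 3.87 RPKM), MSX1 (0.247 and 1.51 RPKM) and ID1 (87.8 and 203 RPKM), with a median of 0.74 at the 99.94th percentile. ID3 (132 and 67.6 RPKM) and ID2 (70.8 and 60.9 RPKM) went down, and ID4, SMAD6 and BAMBI went up, all by less than 2-fold.

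Markers of other lineages were mixed and mostly low. Of 11 neuroectoderm genes 5 were at least 2-fold higher, with a median of 0.57 at the 99.78th percentile. HESX1, an anterior homeobox gene also expressed in anterior endoderm, was at 1.75 and 8.55 RPKM, PAX6 at 0.144 and 1.70 RPKM, OTX1 at 1.47 and 3.91 RPKM, and LHX2 at 0.0736 and 0.947 RPKM. TUBB3, NES and SOX3, the members with the highest RPKM, were lower by less than 2-fold and are named after their values were seen. Their log2 fold changes were -0.90, -0.22 and -0.21, and all other members of the neuroectoderm list were higher. With genes below a mean of 2 RPKM left out, this list fell within the random range at the 95.3rd percentile. Of 8 mesoderm genes HAND1 was higher (0.325 and 2.10 RPKM) and KDR lower (22.9 and 9.95 RPKM). The mesoderm median was 0.47, at the 98.8th percentile. With no expression minimum it was 0.25, with the same call. Too few members had a mean of at least 2 RPKM for that setting. Medians of 0.08 for 6 trophoblast genes and -0.05 for 7 extraembryonic and visceral endoderm genes lay within the random range. TFAP2A (0.229 and 4.20 RPKM) and GATA3 (0.613 and 2.28 RPKM) of the former, and the apolipoprotein genes APOA1 (12.8 and 28.8 RPKM) and APOA2 (2.56 and 7.60 RPKM) of the latter, were at least 2-fold higher. Of 3 HOX genes that passed the expression minimum, HOXB2 was at 1.78 and 5.47 RPKM, HOXB1 at 0.647 and 1.00 RPKM and HOXB13, named after its values were seen, at 1.08 and 0.453 RPKM.

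Epithelial genes had a median of -0.14 within the random range, with EPCAM higher (37.2 and 110 RPKM) and CLDN4 lower (38.7 and 11.2 RPKM). Of 8 mesenchymal genes 3 were higher and 2 lower, with a median of 0.44 at the 97.9th percentile that fell within the random range with a pseudocount of 1. The cadherin gene CDH2 was at 14.4 and 39.5 RPKM, ZEB1 at 0.394 and 1.77 RPKM and ZEB2 at 0.307 and 1.51 RPKM, while FN1, the fibronectin gene, was at 72.5 and 27.4 RPKM. Of 8 measured fibroblast and stromal genes 4 were at least 2-fold lower and 2 higher. The lower ones were THY1, a surface protein also present on hESCs (260 and 45.9 RPKM), S100A4 (13.6 and 2.88 RPKM), and the collagen genes COL1A1 (18.2 and 6.47 RPKM) and COL1A2 (18.4 and 7.59 RPKM). Their list median lay below all matched random lists (central 95% from -0.47 to 0.45), but was -0.07 with all 10 members included and no expression minimum.

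**Figure D2:**
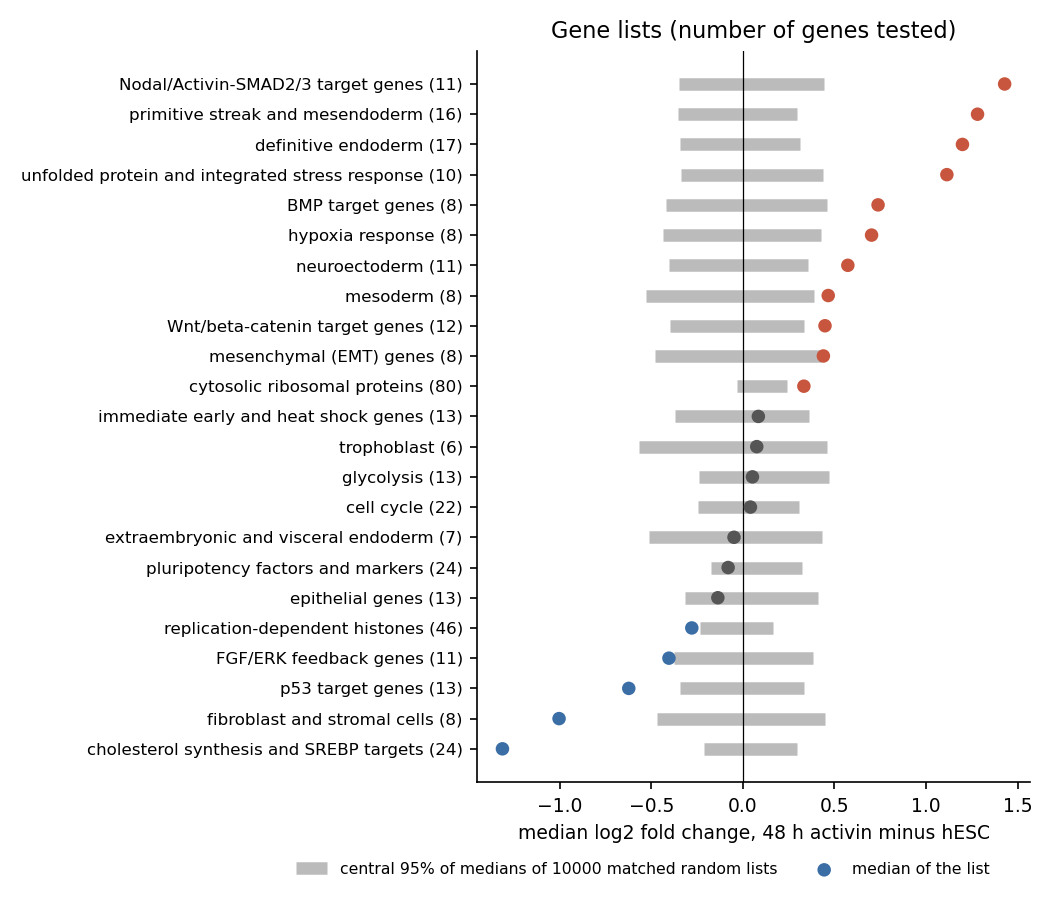
For each of 23 gene lists with at least 5 tested genes, the point is the median log2 fold change (48 h activin minus hESC) and the grey bar the central 95% of medians of 10000 random lists matched on mean RPKM; red points lie above the bar, blue points below it and dark grey points within it. Nodal/activin targets have the highest median (1.43) and cholesterol synthesis and SREBP targets the lowest (-1.31).

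The medians of 22 cell cycle genes (0.04) and 13 glycolysis genes (0.05) lay within the random range, and no member of either list differed 2-fold. PCNA was at 170 and 121 RPKM, MCM7 at 108 and 128 RPKM, ENO1 at 884 and 1032 RPKM and GAPDH at 2277 and 2829 RPKM. The 80 cytosolic ribosomal protein genes had a median of 0.33, at the 99.92nd percentile, with 12 at least 2-fold higher and 2 lower. With quantile normalization the median was 0.18, still above its random range. RPS29 had a log2 fold change of 3.14 (1.20 in its other row), RPL38 2.05, RPL31 1.80 and RPS7 1.59, and RPS29 and RPL31 have 33 and 64 named pseudogenes. Of the 23 lists, 11 lay above and 5 below their random range.

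The second comparison addressed genes that start from opposite strands near each other. The table held no rows of the RefSeq noncoding class, so the planned fold changes of lncRNA/mRNA pairs, and of lncRNA genes as a class, could not be computed. Of its gene names 32 are now classed as lncRNA, and 7 of these passed the expression minimum, MIR205HG among them. None of the 24 named lncRNAs fixed in advance had a row. Head-to-head mRNA/mRNA pairs were used instead. Over 720 pairs of measured mRNAs with 5′ ends within 2000 bp, the fold changes of the members correlated weakly across pairs, with Pearson's r of 0.25 (bootstrap 95% interval 0.18 to 0.32) and Spearman's rho of 0.24. Partners exchanged at random 100000 times gave r between -0.07 and 0.07 in 95% of draws and at most 0.15. Neighbours in other orientations also correlated, with r of 0.21 (0.13 to 0.29) over 570 same-strand pairs and 0.14 (0.07 to 0.22) over 586 tail-to-tail pairs. The difference in r between head-to-head and same-strand pairs was 0.04 (-0.07 to 0.15), and between head-to-head and tail-to-tail pairs 0.11 (-0.00 to 0.21), so neither interval excluded 0. These are relations across genes, and genes are not independent replicates. The members of 435 head-to-head pairs (60.4%, exact interval 56.7 to 64.0%) differed in the same direction, against 51.5% with exchanged partners. For tail-to-tail pairs the share was 56.5% (52.4 to 60.5%) against 50.8%. Same-strand pairs had 56.0% (51.8 to 60.1%) against 52.1%. Both intervals overlap that of head-to-head pairs.

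Both members differed at least 2-fold in only 4 head-to-head pairs, which are named here after their values were seen. The histone genes HIST1H2BC and HIST1H2AC, whose 5′ ends lie 240 bp apart on chromosome 6 (26232111 and 26232352), were both lower, with log2 fold changes of -1.18 and -1.48. PYY and NAGS, 194 bp apart on chromosome 17, were both lower, at -1.03 and -1.42. CCDC92 and ZNF664, 598 bp apart on chromosome 12, were both higher, at 1.29 and 1.06. NDUFA7 and RPS28, 103 bp apart on chromosome 19, differed in opposite directions, at -1.02 and 1.10. None of the 14 marker genes was in these pairs.

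The third comparison took the assembled RNA pools, which held noncoding and other RNA outside the mRNA table. No record of either pool overlapped the span of a listed mRNA on the same strand. In the hESC pool 110871 records were read and in the 48 h pool 152483, of 3 kinds by name: Cufflinks, Scripture, and records starting with F, whose origin is not stated. The hESC pool broke off within a Scripture record, so its Scripture part is incomplete, and 53518 F records were identical in both pools. Only Cufflinks records, 23884 in the hESC pool and 23862 in the 48 h pool, were therefore used for records at mRNA genes. Of these, 3626 and 2907 were spliced, and the median span was 980 and 792 bp.

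A minority of expressed mRNA genes had a divergent record upstream, but such records were more frequent than records on the mRNA's own strand. In the hESC pool 1282 of 13049 expressed mRNA genes (9.82%, exact interval 9.32 to 10.3%) had the 5′ end of an opposite-strand Cufflinks record within 2000 bp upstream. In the 48 h pool 1433 genes did (10.5 to 11.5%). The median distance was 302 bp in hESC and 375 bp at 48 h. The number of genes was 1.12 times as high at 48 h (bootstrap interval 1.06 to 1.18). This interval and the next resample genes within 1 pool per condition and cover no variation between libraries or assemblies. Records on the same strand as the mRNA that ended within the same distance upstream were found at 223 genes (1.71%) in hESC and 266 genes (2.04%) at 48 h, a ratio of 1.19 (1.03 to 1.39). Opposite-strand records were thus 5.75 and 5.39 times as frequent as same-strand ones. Because no record overlaps an mRNA on its own strand, same-strand records joined to an mRNA by the assembler are missing from that control. For the same reason a divergent transcript that is itself a listed mRNA is not among the records. Genes with such a neighbour were still counted among the 13049. The excess was largest next to the mRNA: within 250 bp of the 5′ end, 561 genes in hESC had an opposite-strand record and 52 a same-strand one.

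**Figure D3:**
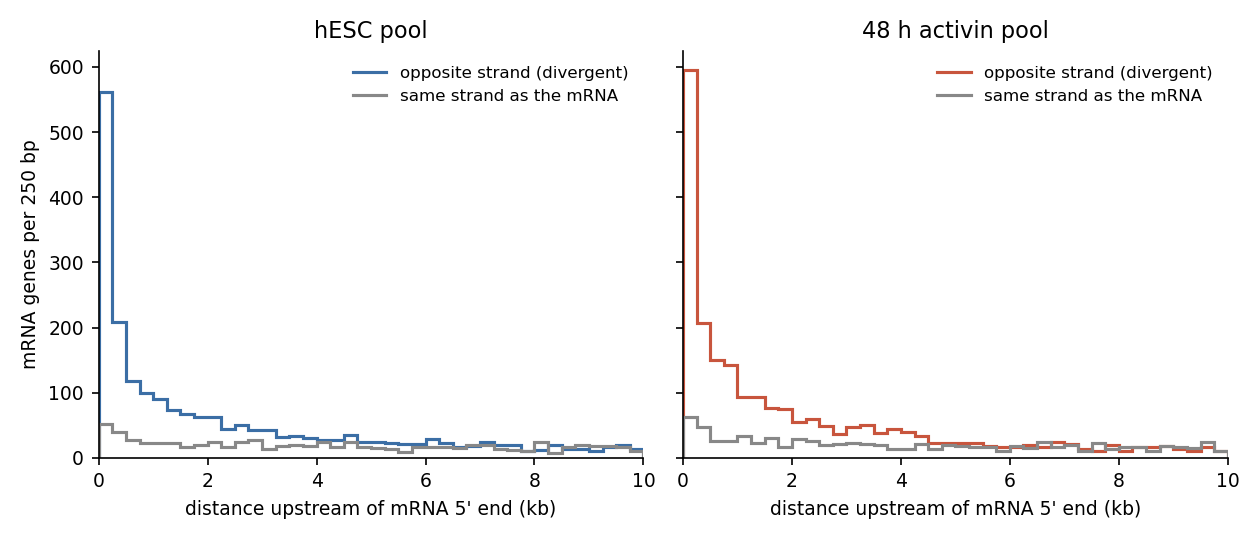
Number of expressed mRNA genes per 250 bp bin by the distance from the mRNA 5′ end upstream to the nearest Cufflinks record on the opposite strand (coloured) or on the same strand (grey), in the hESC pool (left) and the 48 h activin pool (right). In the first bin 561 genes in hESC and 595 at 48 h have an opposite-strand record, against 52 and 63 with a same-strand record.

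The share of mRNA genes with a divergent record followed mRNA level most steeply at the low end. In hESC it was 1.14% (0.828 to 1.52%) among 3866 genes at 0.05 RPKM or less, 4.03% between 0.05 and 0.5 RPKM, 9.66% between 2 and 5 RPKM and 11.3% (9.58 to 13.2%) above 50 RPKM. At 48 h it was 1.13% in the lowest class, 10.6% (9.49 to 11.9%) between 2 and 5 RPKM, highest between 20 and 50 RPKM at 14.4% (12.8 to 16.1%), and 12.8% above 50 RPKM. Same-strand records stayed between 0.435% and 2.88% in all classes of both pools.

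**Figure D4:**
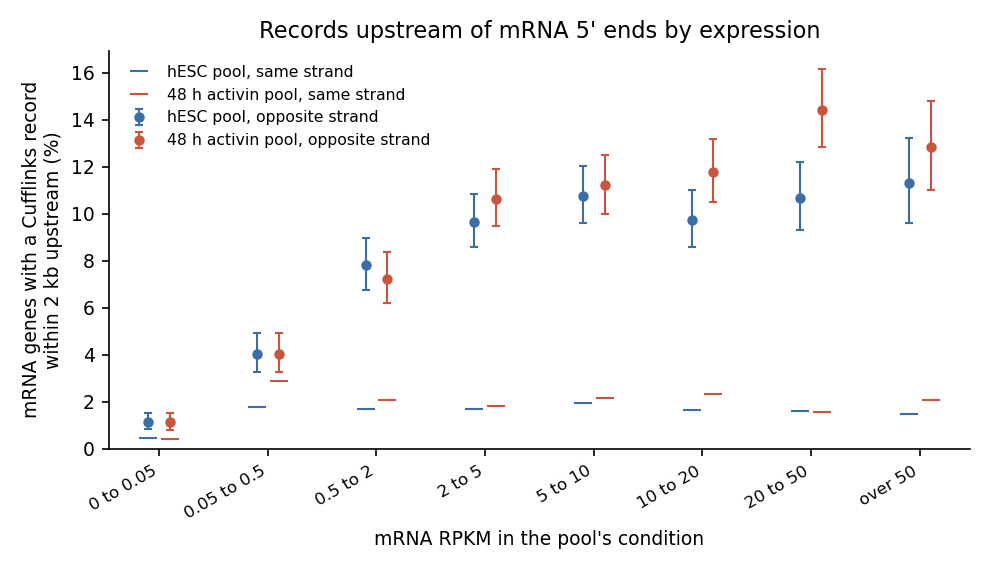
Share of mRNA genes (%) with a Cufflinks record within 2 kb upstream, by mRNA RPKM in the pool's own condition, for the hESC pool (blue) and the 48 h activin pool (red); points are opposite-strand records with exact 95% binomial intervals and dashes are same-strand records. The opposite-strand share goes from about 1% in the lowest class (1.14% and 1.13%) to over 10% in the highest (11.3% and 12.8%).

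Most genes with a divergent record had it in 1 pool alone. Of the expressed genes, 678 had one in both pools, 604 in the hESC pool alone and 755 in the 48 h pool alone. Genes with a record in 1 pool alone had similar median mRNA changes whichever pool held it. Their median log2 fold changes were -0.02 for the hESC pool alone and 0.02 for the 48 h pool alone. The difference of 0.04 lay within the range of -0.07 to 0.07 that 95% of 10000 reassignments of these genes gave. Among genes with a record in the 48 h pool alone, 32 (4.24%, 2.92 to 5.93%) were at least 2-fold higher and 23 (3.05%, 1.94 to 4.54%) lower. Among those with a record in the hESC pool alone, 20 (3.31%, 2.03 to 5.07%) were higher and 33 (5.46%, 3.79 to 7.59%) lower. Among 11012 genes with a record in neither pool, 3.69% (3.34 to 4.06%) were higher and 5.24% (4.83 to 5.67%) lower. Differences between these shares were not tested. Same-strand records too were more often in the 48 h pool alone (177 genes) than in the hESC pool alone (134 genes).

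Among genes with a divergent record in 1 pool, those with the largest mRNA differences went both ways. FEZF1, a forebrain zinc finger gene (chromosome 7, 5′ end at 121731801), was at 3.72 and 14.7 RPKM. At 48 h it had a divergent Cufflinks record of 6 exons at 121732175 to 121741796, starting 373 bp upstream. GREB1L (chromosome 18, 5′ end at 17076201) was at 0.608 and 3.20 RPKM, with a 1111 bp record 349 bp upstream at 48 h, and SEC61G was at 29.7 and 186 RPKM, with a 384 bp record 184 bp upstream at 48 h. FASN and S100A6, both lower at 48 h, had a record at 48 h alone, 1496 bp and 411 bp upstream. Of the genes with a record in hESC alone, MMP17 (chromosome 12, 5′ end at 130878894) was at 19.4 and 5.09 RPKM with a 2-exon record 67 bp upstream, and SLC17A9 at 15.0 and 2.33 RPKM with a 301 bp record 65 bp upstream. CEBPB (6.97 and 29.7 RPKM), INSM1 (0.784 and 4.19 RPKM) and ZNF503 (0.432 and 3.53 RPKM) were higher at 48 h although their Cufflinks record within 2000 bp was in hESC alone. At INSM1 and ZNF503 the 48 h pool had a record just outside the window, at 2042 bp and 2041 bp. At FEZF1, SLC17A9 and ZNF503 an F record that was the same in both pools also began within the window (393, 42 and 289 bp), so presence in 1 pool holds for Cufflinks records only.

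None of the 14 marker genes had a divergent Cufflinks record within 2000 bp in either pool, and 2 had a record of another kind. GATA6 had a divergent Scripture record in both pools: 5 exons at chromosome 18, 17999746 to 18003006, starting 407 bp upstream in hESC, and 4 exons at 18000626 to 18002930, starting 483 bp upstream at 48 h. An F record of 3 exons at 18002080 to 18002927, 486 bp upstream, was the same in both. GSC had a 2-exon Scripture record at 48 h, at chromosome 14, 94306669 to 94308916, starting 416 bp upstream. The Scripture part of the hESC pool being incomplete, its lack there is not informative. Cufflinks records began further upstream of GATA6 in both pools (3795 bp in hESC and 3825 bp at 48 h), and of SOX17 (3144 bp) and NANOG (2319 bp) at 48 h.

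Divergent starts were also counted among the records themselves. Merging overlapping same-strand records of all kinds gave 35197 loci in hESC and 37124 at 48 h. Of these, 1275 (3.62%, 3.43 to 3.82%) and 1432 (3.86%, 3.66 to 4.06%) lay head to head with an opposite-strand locus within 2000 bp. Tail-to-tail neighbours within the same distance made up 2.64% and 3.05%. Strands permuted among the loci of each chromosome gave 15.4% and 17.1% on average, above the observed share in all 1000 draws. Tail-to-tail shares lay below it too, so this reference says nothing on divergent starts in particular. The incomplete Scripture part and the F records shared by both pools enter all these values. Of the hESC loci 67.5% (67.0 to 68.0%) were covered over at least 50% of their length by a locus of the 48 h pool, and 69.7% (69.2 to 70.2%) the other way. With Cufflinks records alone these shares were 37.8% and 49.7%.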

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

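Settings that used Cufflinks records alone, the median over the rows of a gene, genes without pseudogenes, length-matched lists, and every setting of mRNA pairs and of records at mRNA genes were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The limma settings, camera and fry, the adjusted threshold, the replicate block, leaving out each library and a count test were not run, nor was any setting for lncRNA genes or lncRNA/mRNA pairs, for lack of values per library or of rows with a noncoding accession. The number of genes at 2-fold or more was 1143 and stayed within 1.5 times of this, from 813 (pseudocount 1) to 1569 (pseudocount 0.1), except that every row of the file gave 1974, from 23498 rows tested. Quantile normalization and median-ratio scaling moved the share of higher genes among these from 41.6% to 43.7% and 39.9%. The number of lists apart from random lists was 16, and 13 to 16 under the alternatives. The 13 came with a mean of at least 2 RPKM, where 20 lists could be tested. There the mesoderm and mesenchymal lists, both higher in the main setting, and the trophoblast list had too few genes. With no expression minimum the 16 held the HOX list (39 genes, median 0.27) and not the fibroblast list. Of 181 list values under an alternative 178 had the same call and the other 3 are given with their lists. None of the 16 lists of the text changed sign. Of 676 values of named genes under an alternative, 668 stayed on the same side of 2-fold; POU5F1 reversed, from 1.09 to -0.15, with the median over its rows, and was at 0.83 with quantile normalization. Of the other genes, FN1 lost its 2-fold call with that median, and ZEB1, ZEB2, LHX2, OTX1 and HIST1H2BC lost theirs at pseudocount 1. For head-to-head mRNA pairs r stayed between 0.21 and 0.27 and the same-direction share between 60.2% and 61.5%. Genes with a divergent Cufflinks record, 1282 in hESC and 1433 at 48 h, numbered 987 and 1094 within 1000 bp and 1735 and 1929 within 5000 bp.

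Pool shares moved with every setting, and the cause was not tested. The head-to-head share of loci (3.62% in hESC, 3.86% at 48 h) was 2.41% and 2.57% within 1000 bp, 6.46% and 7.04% within 5000 bp, 1.99% and 2.07% for spliced loci, 5.48% and 6.06% for single transcripts, and 3.42% and 3.33% for Cufflinks records; in each it exceeded the tail-to-tail share. The shared portion of loci (67.5% of hESC, 69.7% of 48 h) was 75.3% and 74.2% at 1 bp of overlap, 58.4% and 62.3% at 90%, 83.6% and 79.1% for spliced loci, and 37.8% and 49.7% for Cufflinks records. Depth is a limit on the pools, since a record needs enough reads to be assembled: the 48 h column stood on 0.679 times the reads of the hESC column.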

Other observations

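Except for the tests of ribosomal protein genes, the tests below were chosen after the results were seen. Genes below outside the rule for names were chosen after their values were seen. Divergent records were unevenly spread over the gene lists. Of 13049 expressed genes, 15.6% had a divergent Cufflinks record within 2000 bp in at least 1 pool. In the cholesterol synthesis and SREBP list it was 11 of 24 genes (45.8%), against 18.1% in random genes matched on mean RPKM, at the 99.96th percentile. Among these were FASN, SCD, the squalene synthase gene FDFT1, and FDPS, MVD, LSS, MSMO1, CYP51A1 and SC5DL. Among 8 mesenchymal genes 5 had one (VIM, FN1, ZEB1, SNAI2 and TWIST1, 99.9th percentile), and among 8 mesoderm genes 4 (KDR, FOXC1, SNAI2 and TWIST1, 99.4th percentile). None of the 11 Nodal/activin target genes had one, where matched genes would give 17.3%; that is the 6.07th percentile and lies within the random range. In the definitive endoderm list 3 of 17 genes had one (HHEX, GATA4 and FOXA1, 64.6th percentile), and in the pluripotency list 4 of 24 (DPPA4, UTF1, FOXD3 and TERT, 43.9th percentile). These were 23 lists looked at together.

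Large fold changes of ribosomal protein genes were a pattern of the mRNA table. The median absolute log2 fold change of the 80 genes was 0.51, above the 0.27 to 0.46 of lists matched on mean RPKM. This measure is taken about 0, so the list's upward shift (median 0.33) enters it. A spread about the list's own median was not tested. Short transcripts stay open as an explanation. The measure stood at the 98.51st percentile, just past the upper bound set in advance, when lists were matched on transcript length too. The lengths at hand, however, are the shortest that fit the reads (60 for RPL12 and 76 for RPL37A) and do not control true length. Reads shared with pseudogenes stay open as well. Outside the list, 270 genes with at least 5 named pseudogenes had a median absolute change of 0.39, at the 78.65th percentile of lists matched on both, neither high enough nor low enough to decide, and 74 of the 80 ribosomal genes have at least 5, which leaves too few without. The 2 RPS29 rows, with log2 fold changes of 3.14 and 1.20, show that the choice of transcript alone moves a value by more than 2-fold, and no biological explanation was tested.

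The lower level of cholesterol synthesis and SREBP genes may come from activin, from the stage reached, or from the medium. A trend with expression level or with the recovered transcript length is argued against, since the median was -1.35 after the median of genes of the same RPKM and length was subtracted, below all random lists (central 95% from -0.28 to 0.24). Activin and the change from mTeSR1 to RPMI-B27 cannot be told apart, because 0 of the 2 RPKM columns come from RPMI-B27 cells without activin. Every other difference between these columns shares that limit. Examples are the higher Nodal/activin targets, the lower FGF/ERK feedback genes and the higher DDIT3, CHAC1, ASNS and TRIB3. The series also holds a GRO-seq sample of RPMI cells at 0 h of activin. It was not analysed here, so whether it separates medium from activin was not examined.

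A hypothesis was that a divergent RNA and its mRNA appear or disappear together. If so, genes with a divergent Cufflinks record at 48 h alone would have higher mRNA fold changes than genes with one in hESC alone. The difference of medians, 0.04, stood at the 87.86th percentile of 10000 reassignments, in that direction but within the range that chance gives. Genes at 2-fold or more were 32 higher and 23 lower for 48 h alone, against 20 higher and 33 lower for hESC alone. These counts also went in that direction and were not tested. A record is a yes-or-no call that depends on depth, so a link at single genes such as FEZF1 is neither shown nor excluded, and levels of the divergent RNAs were not at hand.

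More mRNA genes had a divergent Cufflinks record at 48 h than in hESC (1433 and 1282). Of the genes with a record in 1 pool alone 55.6% (52.9 to 58.2%) had it in the 48 h pool, but this share follows from the counts above and tests nothing, so an effect of the lower number of reads at 48 h stays open. The pools held about as many Cufflinks records (23884 in hESC and 23862 at 48 h). Upstream records on the same strand were also at more genes at 48 h. Their ratio was 1.19 (1.03 to 1.39) against 1.12 (1.06 to 1.18) for divergent ones, with intervals from resampled genes alone. The first form of that control, by 5′ ends, gave a ratio of 1.25. Within 5000 bp the order turned, with 1.07 for same-strand and 1.11 for divergent records, so whether records of any orientation explain the difference stays open. A difference particular to divergent RNA is not shown. Breakage of transcripts into more and shorter records at lower depth could add to both and was not tested, and no biological explanation was tested.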
